A study of Mus musculus with 6 samples.

How the data were processed

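The data came from 6 microarrays of CT26 cells, a mouse colorectal cancer line, carrying either a short hairpin RNA against TGF-β1 or a control hairpin, stably transfected per the labels. Each line was harvested at 24, 48 and 72 h, with 1 array per line and time point, and per the labels the cultures were grown and harvested separately. Total RNA was labelled with the Hy3 dye at the 3' end and hybridised to a locked nucleic acid miRNA array read in 1 colour, per the labels' protocols. The scanner software, the array version and a genome build were not given in the sources used here, and no coordinates are printed.

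Per the file headers, the authors deposited a foreground intensity and a background-subtracted intensity for each of 15840 spots on each array. The intensities were not scaled between arrays. The table held 1126 mouse miRNA probes with 4 spots each, 57 viral miRNA probes, 2256 unnamed probes, 62 spike-in control probes, 23 probes for other small RNAs, 7 negative control probes and 1132 empty spots. A second table deposited by the authors held a ratio per probe. Set against the intensities, each ratio equalled the median background-subtracted intensity of the probe's spots divided by 1 number per array, between 313.5 and 397, within a relative tolerance of 1e-06 for 100% of the filled values. The ratio was blank where that median was not above 0. Column medians of the ratio ran from 0.259 in the control array of 24 h to 0.514 in that of 48 h, with no centring of probes, and how the scaling numbers were chosen stays unknown. Columns were assigned to samples by the sample number in the labels.

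Background was corrected by normexp with an offset of 50 in limma 3.58.1 under R 4.3.3. Spots of a probe were averaged on the log2 scale, and arrays were quantile normalised over the 3439 mouse, viral and unnamed probes. A mouse probe was tested where its mean background-subtracted intensity was at least 50 on at least 3 of the 6 arrays. This kept 372 probes and left out 754. Probe names are those of the array's design, and 10 tested probes carried more than 1 name. After quantile normalisation the probe of miR-5100 held the same value on all 6 arrays.

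The knockdown was compared with the control in limma with the time point as a factor and moderated variances with a trend and robust estimation. The adjustment was by Benjamini-Hochberg at 0.05 over the tested probes. A slope per day with the line as a covariate asked about time, and the product of line and time asked whether the slopes differed. Differences at a single time point rest on 1 array of each line and have no test. They were described by size at 2-fold over probes with an intensity of at least 50 on at least 1 of the 2 arrays, with the standard error over replicate spots, which covers spot noise only. A side below 50 gave only a bound, computed against the higher of the probe's own value and the lowest normalised value among mouse probes at or above 50 on that array. Where the probe's own value was the higher, the ratio is the measured one and bounds nothing.

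Before the data were examined, 22 miRNA lists were fixed from general knowledge of families, clusters, TGF-β signalling and tissue markers. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, all two-sided, and 21 lists had at least 2 tested probes. Also fixed were the alternatives and the rule for naming miRNAs. The rule took every probe past the threshold and otherwise filled up to 10 higher and 10 lower probes with the largest mean difference among those of the same sign at all 3 time points, as values. It further took up to 2 members in each direction per list, the 3 smallest p-values for each slope where none passed, and the 3 largest differences in each direction at each time point. The alternatives covered the background correction, the offset, the scaling, the filter, the probe set, the authors' ratios with 0.15 added before log2, the variance model, the time block, the fold threshold and leaving out each time point. Array weights and a term for the line at a single time point, which leaves 1 residual degree of freedom, were added after the data were seen.

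The time points come from the labels and enter as the block. Deviations of the 2 arrays of a time point from their line means correlated at -0.30 at 24 h, -0.52 at 48 h and -0.34 at 72 h across probes, so arrays of the same time did not deviate together.

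The models were tested on simulated data drawn from the real probe means and spreads, independent between probes. With 40 of 372 probes changed, the knockdown comparison recovered 3.38% at 2-fold, 49.6% at 4-fold and 96.0% at 8-fold. The slope per day recovered 37.4% at 2-fold per day, and the difference of slopes 32.8% at 4-fold per day. The term for the line at 48 h recovered 8.88% at 8-fold and 42.4% at 16-fold, so its count at a time point says little about smaller differences. A 2-fold shift of the 10 tested let-7 probes was called in 100% of 20 draws. Members of the real lists were not independent: the estimated correlation was 0.06 in the let-7 family and 0.99 in the miR-15/16 family. The 100% therefore holds for independent probes only. With no probe changed, the knockdown comparison made at least 1 call in 28 of 100 draws when each probe kept its own spread, and in 6 of 100 when spreads lay on the fitted trend. Single calls from this design, with 2 residual degrees of freedom, are therefore less certain than the adjusted p states. Which probes made the calls was not tested. P-values measure the spread between these arrays, with the 3 time points as the only replication, and the number of arrays limits the precision.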

Results

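The study measured miRNAs in CT26 mouse colorectal cancer cells that carry a short hairpin RNA directed against TGF-β1, a secreted cytokine that acts through SMAD transcription factors, and in CT26 cells with a control hairpin. Each line was sampled at 24, 48 and 72 h, giving 3 arrays per line; the labels word these times as hours transfected but also call the transfection stable, so what they count from is unsettled. Between 321 and 374 of the 1126 mouse probes had an intensity of at least 50 on an array, the fewest on the control array of 48 h. Median background ran from 89 to 181, the highest on that same array. On the control array of 72 h mean background was 127 against a median of 100, a wider gap than on any other array. The array carries miRNA probes, so the Tgfb1 transcript, and with it the knockdown itself, was not measured and the labels could not be checked against it. Across the 372 tested probes the correlation between arrays lay between 0.43 and 0.85. It averaged 0.66 within a line and 0.70 between lines.

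**Figure D1:**
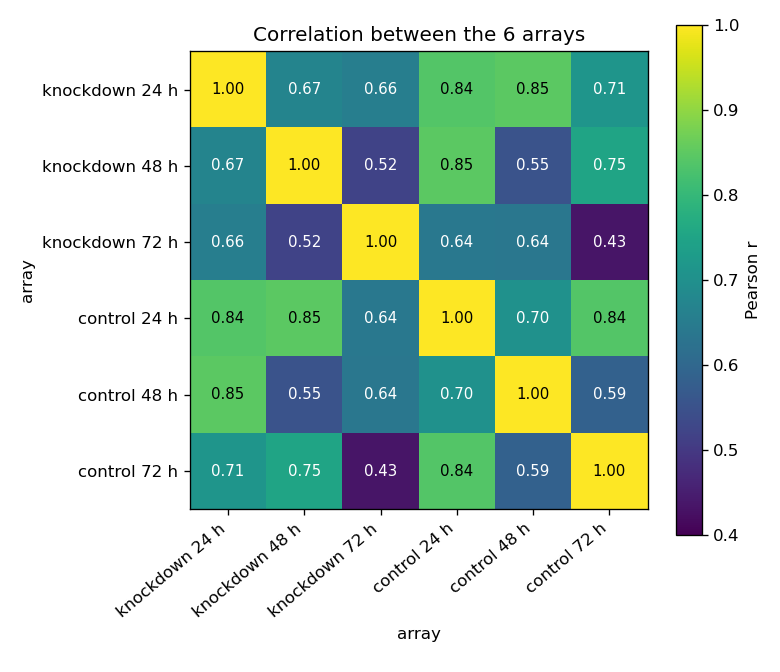
Pearson correlation between each pair of the 6 arrays over the 372 tested mouse probes, with arrays on both axes and r given in each cell. The lowest value, 0.43, joins the knockdown and control arrays of 72 h, and the highest, 0.85, joins the knockdown array of 24 h and the control array of 48 h.

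The first comparison asked which miRNAs differ when TGF-β1 is knocked down. Of the 372 miRNA probes, 0 changed past the threshold in limma, and 1, miR-592-3p, had an unadjusted p under 0.05, where 18.6 would be expected by chance. Simulations without any change, each probe at its own spread, gave 5.16% of probes under 0.05. They lacked the opposite 48 h differences described below. The probe of miR-33-5p, a miRNA encoded in an intron of Srebf2 that represses cholesterol export genes, had a mean log2 intensity of 9.73 ± 0.73 (SD, n = 3) in the knockdown and 10.97 ± 0.58 (SD, n = 3) in the control. Its difference was -1.24 with a 95% interval from -2.60 to 0.11 (limma adjusted p = 0.998). The probe of miR-207 stood at 11.11 ± 0.91 (SD, n = 3) in the knockdown and 9.87 ± 0.20 (SD, n = 3) in the control, a difference of 1.24 with an interval from -0.15 to 2.63 (limma adjusted p = 0.998). For miR-207 the differences at 24, 48 and 72 h were 0.51, 0.88 and 2.34. All 20 miRNAs named for this comparison had the same sign at the 3 time points, by the rule that chose them, and the smallest adjusted p over all tested probes was 0.998.

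On the higher side, miR-875-3p differed by 1.14, miR-667-3p by 1.04, miR-592-3p by 0.96, miR-340-5p by 0.95 and miR-1983 by 0.84 on the log2 scale. The differences of miR-3473a, miR-669k-5p, miR-5097 and miR-147-3p lay between 0.72 and 0.82. For miR-875-3p the difference was 0.06 at 24 h, 0.51 at 48 h and 2.83 at 72 h, whereas for miR-1983 it was 0.84, 0.64 and 1.05. At 72 h miR-667-3p differed by 2.50, miR-592-3p by 1.95, miR-3473a by 1.47 and miR-669k-5p by 1.80, each more than at 24 or 48 h. Their control values at 72 h were 6.66, 6.39, 6.55 and 6.56. The background-subtracted intensity of miR-592-3p on the control array of 72 h was -495, so its local background was far above that array's median of 100. The lowest mouse probe with an intensity of at least 50 on that array stood at 7.75. On the lower side, miR-211-5p, encoded in the melanocyte gene Trpm1, differed by -1.19, miR-99a-5p by -1.11, miR-1843a-5p by -1.10 and miR-3084-5p by -1.08. The related miR-199a-5p and miR-199b-5p differed by -0.90 and -0.86, miR-23b-3p by -0.89, miR-1949 by -0.76 and miR-714 by -0.76. The mean of miR-1949 was carried by 72 h, with differences of -0.02, -0.19 and -2.08 at 24, 48 and 72 h. For miR-199a-5p the difference was -0.79 at 24 h, -1.23 at 48 h and -0.67 at 72 h. Of the 20, 14 had an intensity of at least 50 on all 6 arrays and 6 on 4 or 5. None of these passed the test, and the 95% interval of a typical probe reached 1.29 to either side. miR-712-3p, chosen after its values were seen, had an intensity of at least 50 on all 3 control arrays and under 50 on the 3 knockdown arrays. Its mean was at least 1.18-fold higher in the control (limma adjusted p = 0.998). The cutoff parted a highest knockdown intensity of 49.5 from a lowest control intensity of 62.5. At 24 h both lines had a normalised value of 7.74, so that time point showed no difference.

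**Figure D2:**
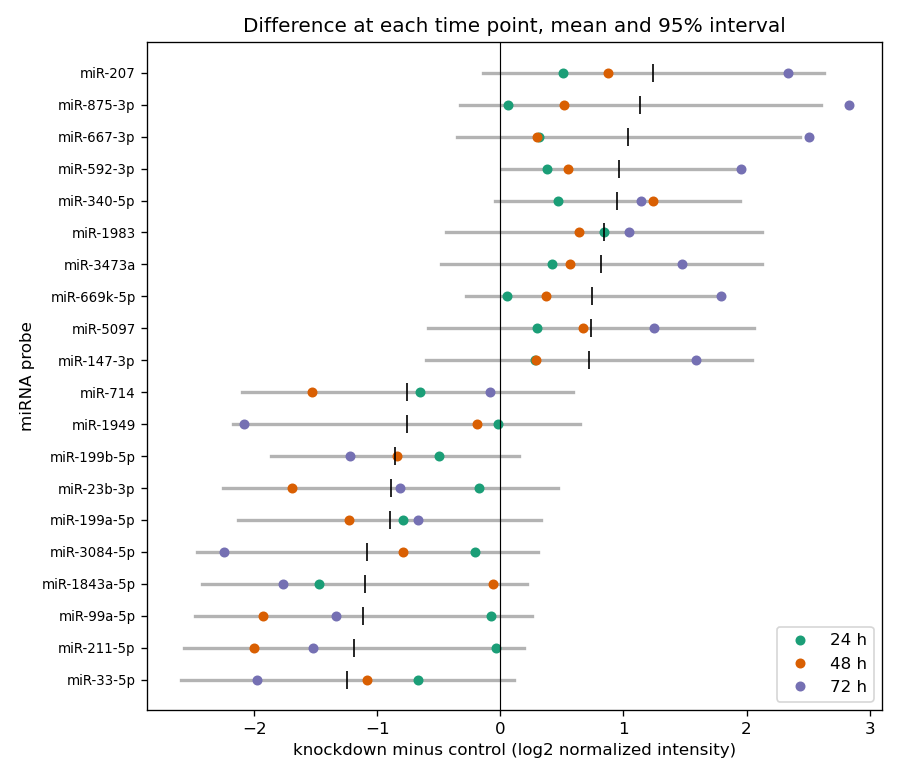
Knockdown minus control difference in log2 normalised intensity (x axis) for the 20 miRNAs named in the main comparison (y axis). Coloured points are the 24, 48 and 72 h differences, the vertical tick is their mean and the grey bar its 95% interval from limma. Only the interval of miR-592-3p leaves out 0, from 0.01 to 1.91, and this probe was not well above background on the control arrays of 48 and 72 h.

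Leaving out the 48 h arrays changed the count of called miRNAs, and 37 probes then had an unadjusted p under 0.05. Without them 3 miRNAs were lower in the knockdown in limma: miR-3096a-3p with a mean difference of -3.34 (adjusted p = 0.00840), miR-195a-5p with -2.84 (adjusted p = 0.0339) and miR-222-3p, which with miR-221 represses the cell cycle inhibitor Cdkn1b, with -2.86 (adjusted p = 0.0431). At 48 h all 3 probes were higher in the knockdown, miR-195a-5p by 1.51 on the log2 scale and miR-3096a-3p by 19.4-fold as measured. The probes of miR-3096a-3p and miR-222-3p were not well above background on the control array of 48 h, nor that of miR-222-3p on the knockdown array of 72 h, so the size for miR-222-3p without 48 h takes in such a value. That fit holds 4 arrays, and in simulations without any change it made at least 3 calls in 7 of 100 draws when each probe kept its own spread, and in 0 of 100 when spreads lay on the fitted trend.

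The miRNA lists asked whether families and clusters moved together. None of the 21 lists tested passed the threshold with camera, with an estimated correlation or with fry, and no list had a member past the threshold adjusted over the list alone or over all probes. With camera 1 list, the Dlk1-Dio3 cluster, had an unadjusted p under 0.05, and none did with an estimated correlation or with fry. All 10 tested probes of the let-7 family, which represses Ras and Hmga2, had a negative mean difference, with a median of -0.36 (camera adjusted p = 0.395). At single time points the let-7 median was -0.13, 0.44 and -1.06. let-7b-5p differed by -0.75 and let-7e-5p by -0.68. Of the 63 distinct members that the naming rule took from the lists, 31 were not well above background on at least 1 array, so their mean differences are approximate.

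Of the miRNAs reported in the literature to be induced by TGF-β, 5 of 14 had a positive and 9 a negative difference, with a median of -0.19 (camera adjusted p = 0.624). They ran from miR-27a-3p at 0.28 and miR-24-1-5p at 0.22 to miR-24-3p at -0.68 and miR-199a-5p at -0.90. Those reported to be repressed by TGF-β divided into 8 and 8, with a median of -0.06 (camera adjusted p = 0.821). miR-29b-3p, a repressor of collagen genes, differed by 0.47 and miR-30e-5p by 0.40, and miR-34a-5p by -0.83 and miR-30c-5p by -1.16. In the miR-200 family, which restrains the mesenchymal regulators Zeb1 and Zeb2, only 2 of 12 probes were tested, miR-200c-3p at 0.35 and miR-141-5p at 0.02 (camera adjusted p = 0.720). The miR-200c-3p differences were -0.01, -0.57 and 1.65 at 24, 48 and 72 h, the last against a control value below background, and without 72 h the family median was -0.17. The miR-29 family had a median of 0.15 over 5 probes, with miR-29c-3p at 0.35, miR-29b-1-5p at -0.26 and miR-29a-5p at -0.59 (camera adjusted p = 0.857). The miR-30 family had a median of -0.37 over 7, with miR-30b-3p at 0.13 and miR-30d-5p at -0.62 (camera adjusted p = 0.624).

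Among growth and stress miRNAs, the miR-15/16 family had a median of -0.48 over 4 probes, with miR-195a-5p at -1.39 and miR-15b-5p at -0.49 (camera adjusted p = 0.472). Its medians at 24, 48 and 72 h were -1.39, 2.11 and -2.50. All 5 tested probes of the p53-linked list were below 0, with a median of -0.52, among them miR-34a-5p and, at -0.72, miR-34b-5p (camera adjusted p = 0.395). The 3 probes of miR-221 and miR-222 had a median of -0.38, with miR-222-3p at -1.02 and miR-221-5p at -0.38 (camera adjusted p = 0.624). The miR-17-92 and paralogous clusters divided into 6 and 6 with a median of -0.08, from miR-19b-3p at 0.88 and miR-25-3p at 0.53 to miR-93-5p at -0.65 and miR-106b-5p at -0.74 (camera adjusted p = 0.857). The hypoxia and stress list had a median of -0.05, with miR-132-5p at 0.49, miR-22-5p at 0.36, miR-22-3p at -0.56 and the hypoxia-induced miR-210-3p at -0.84 (camera adjusted p = 0.821). Camera's direction for the last 2 lists was up, against a median below 0.

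The Dlk1-Dio3 cluster, an imprinted miRNA locus, had 13 of 22 probes above 0 and a median of 0.16 (camera adjusted p = 0.191, and adjusted p = 0.913 with an estimated correlation). The unadjusted camera p was 0.00910 at the preset correlation of 0.01 and 0.103 at the estimated one, -0.00366. Correlation between members thus does not account for the higher p. Its medians at 24, 48 and 72 h were 0.03, -0.04 and 0.51, so the shift lay mainly at 72 h. There miR-667-3p differed by 2.50 against a control value below background. miR-667-3p and miR-665-3p differed by 1.04 and 0.98, miR-495-5p and miR-668-3p by -0.50 and -0.59. The Sfmbt2 intronic cluster had 18 of 27 probes below 0 and a median of -0.08, with camera's direction up (camera adjusted p = 0.857). Its ends were miR-669k-5p at 0.74 and miR-669a-3-3p at 0.51 against the shared probe of miR-669a-3p and miR-669o-3p at -0.45 and miR-467a-5p at -1.01. The miR-467a-5p value was a mean over opposite signs, and this probe was not well above background on 3 arrays. The miR-290-295 cluster had a median of 0.16, from miR-291b-3p at 0.46 and miR-291a-5p at 0.26 to miR-294-5p at -0.15 and miR-290-3p at -0.39 (camera adjusted p = 0.780). The miR-23/27/24 clusters had a median of -0.54 over 7 probes (camera adjusted p = 0.624). The group of miR-10, miR-99, miR-100 and miR-125 had a median of -0.27 over 7, with miR-125b-1-3p at 0.32, miR-99b-3p at 0.21, miR-125a-5p at -0.73 and miR-99a-5p at -1.11 (camera adjusted p = 0.624). The cluster of miR-183, miR-96 and miR-182 had miR-183-5p at 0.13 and miR-183-3p at -0.00115 (camera adjusted p = 0.821), and the miR-181 family had 1 tested probe, miR-181d-5p, at -0.09.

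Markers of other cell types did not pass the test either. Fibroblast and smooth muscle markers had 7 of 9 probes below 0 and a median of -0.27, from miR-214-5p at 0.21 and miR-145a-5p at 0.06 to the miR-199 probes (camera adjusted p = 0.395). Blood cell markers had a median of -0.07, with miR-142-5p at 0.25, miR-155-3p at -0.13 and the shared probe of miR-3107-5p and miR-486-5p at -0.51 (camera adjusted p = 0.857). Muscle, liver and neuron markers had a median of 0.00851 (camera adjusted p = 0.780). They included miR-124-3p at 0.58, miR-122-3p at 0.38, miR-9-3p at -0.33 and miR-1a-1-5p at -0.40. The miR-124-3p mean took in 72 h values that were not well above background in either line. Intestinal epithelium markers had a median of -0.06, with miR-147-3p at 0.72, miR-200c-3p at 0.35, miR-375-3p at -0.47 and miR-375-5p at -0.65 (camera adjusted p = 0.857, direction up). The median over all tested probes was -0.11. Under median scaling the medians of the miR-200, miR-183 and Dlk1-Dio3 lists and of the muscle, liver and neuron markers lay below 0. Under cyclic loess those of the TGF-β-repressed, miR-17-92, hypoxia, blood and intestinal lists lay above 0.

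Without the 48 h arrays, 3 lists passed with camera: the miR-15/16 family with a median of -1.95 (adjusted p = 0.00119), the p53-linked list with -0.99 (adjusted p = 0.0243) and the Dlk1-Dio3 cluster with 0.19 (adjusted p = 0.0243). Each had an adjusted p = 0.693 with an estimated correlation. The simulated lists were run at the preset correlation only, so how often the estimated version can pass with so few arrays is unknown. Its p-values therefore do not show that correlation between members explains these passes. For the Dlk1-Dio3 cluster the median was 0.03 at 24 h and 0.51 at 72 h. With array weights, chosen after seeing the data, the miR-15/16 family and the Dlk1-Dio3 cluster passed with camera (adjusted p = 0.0310 each, and adjusted p = 0.758 with an estimated correlation).

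**Figure D3:**
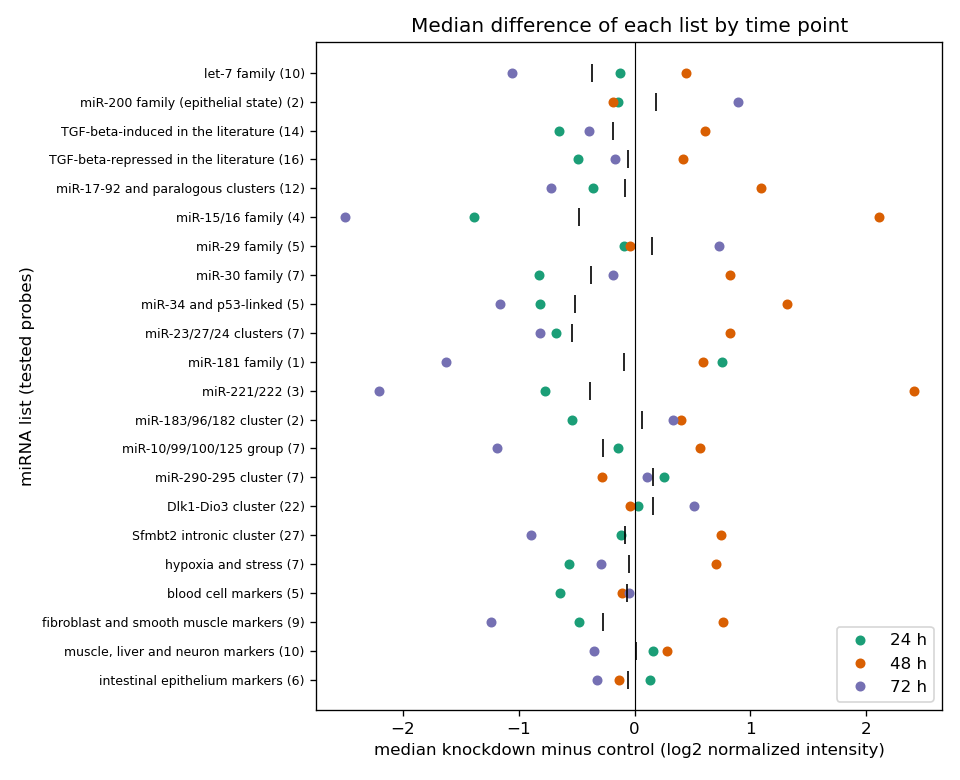
Median knockdown minus control difference in log2 normalised intensity (x axis) for the 22 lists (y axis, number of tested probes in brackets). Coloured points are the medians at 24, 48 and 72 h, and the vertical tick is the median of the mean differences; for the miR-15/16 family the points lie at -1.39, 2.11 and -2.50.

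The next comparison asked which miRNAs move with time in both lines. The neuronal miR-124-3p had a slope of -0.77 ± 0.24 (SE) per day on the log2 scale. It was not well above background on either array of 72 h, so the size of this slope rests in part on such values. Its background-subtracted intensity on the control array of 72 h was -441.5, where median background was 100. High local background on that array may lower such values, which was not tested. miR-669a-3-3p, with an intensity of -151 on the control array of 72 h and so not well above background there, had a slope of -1.08 ± 0.34 (SE). miR-3084-5p, measured on all 6 arrays, had one of -1.01 ± 0.35 (SE). These had the 3 smallest p-values, and none of the 372 probes passed the threshold in limma (smallest adjusted p = 0.999). At an unadjusted p under 0.05 there were 9 probes, where 18.6 would be expected by chance.

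Whether the time course differed between the lines was tested as a difference of slopes. The 3 smallest p-values belonged to miR-467a-5p, with a fitted difference of -3.06 ± 0.98 (SE) per day, miR-744-5p with 2.06 ± 0.70 (SE) and miR-214-5p with -1.18 ± 0.43 (SE). miR-467a-5p and miR-214-5p were not well above background on 3 of the 6 arrays each and miR-744-5p on 1. The sizes of these differences therefore rest in part on such values. None of the 372 probes passed the threshold in limma (smallest adjusted p = 0.931), and 9 had an unadjusted p under 0.05, where 18.6 would be expected by chance. A term for the line at 48 h, chosen after the opposite 48 h differences were seen, passed for 13 miRNAs in limma, all relatively higher in the knockdown at 48 h, among them miR-22-3p by 5.16, let-7g-5p by 4.49 and miR-195a-5p by 4.35 on the log2 scale. These 3 had an intensity of at least 50 on all 6 arrays and the other 10 on fewer. The same term passed for 0 at 24 h and 0 at 72 h, with 1 and 25 probes at an unadjusted p under 0.05, and simulations of the 48 h term without any change made up to 7 calls.

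At single time points, more miRNAs differed between the lines at 48 and 72 h than at 24 h. At 24 h, 46 of 413 miRNA probes differed by at least 2-fold, 11 higher and 35 lower in the knockdown. At 48 h there were 153 of 441, 95 higher and 58 lower, and at 72 h 199 of 454, 84 higher and 115 lower. The split depended on the scaling: under median scaling it was 50 higher and 184 lower at 72 h, and without normalization 19 higher and 29 lower at 24 h. These are differences between 2 arrays with no replicate check, and the median error from replicate spots was 0.14 at 24 h, 0.19 at 48 h and 0.14 at 72 h on the log2 scale. For the probes named below it ran from 0.07 (miR-196b-3p) to 0.33 (miR-467a-5p) at 24 h. At 48 h it ran from 0.05 (miR-193b-3p) to 0.78 (miR-467a-5p), and at 72 h from 0.15 (miR-882) to 0.47 (miR-3081-5p).

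At 24 h miR-467a-5p was at least 8.36-fold higher in the knockdown, miR-196b-3p at least 2.70-fold and miR-24-1-5p 2.75-fold, and miR-3096a-3p was 4.91-fold, miR-195a-5p 4.13-fold and miR-210-3p 3.57-fold lower. At 48 h miR-3096a-3p was 19.4-fold as measured, miR-540-3p at least 6.30-fold and miR-3096b-5p at least 6.06-fold higher. On the lower side at 48 h were miR-193b-3p at least 6.21-fold, miR-467a-5p at least 6.13-fold and miR-328-3p at least 4.77-fold. At 72 h miR-744-5p was at least 10.6-fold, miR-882 9.13-fold and miR-3081-5p at least 5.91-fold higher. The miR-3081-5p intensity on the control array of 72 h was -210 after background subtraction, against a median background of 100. Its local background there was thus high, its control level is unsettled, and the 5.91-fold is not a secure bound. On the lower side at 72 h were miR-222-3p 21.1-fold as measured, miR-3096a-3p 21.0-fold and miR-210-3p at least 10.7-fold. The direction of miR-3096a-3p at 48 h was thus opposite to that at 24 and 72 h.

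The last comparison asked how far the 3 differences agree. Across the 372 probes, which are not independent replicates, the differences at 24 and 48 h correlated at a Pearson r of -0.60 and a Spearman rho of -0.56. Those at 48 and 72 h correlated at -0.27 and -0.22, and those at 24 and 72 h at 0.24 and 0.19. The opposition of 48 and 72 h held over mouse probes under every signal filter run, with rho between -0.27 and -0.18. It depended on adding other probes: rho was 0.00872 with no filter and 0.03 with probes of any species, where r was -0.16 and -0.07. The latter set holds the mouse, viral and unnamed probes that met the signal rule. The sign was the same at all 3 time points for 51 probes, or 13.7%, of which 24 were higher and 27 lower, where independent signs would give 25%. The 3 other ways of exchanging the lines within time points gave 12.4% (72 h exchanged), 33.3% (48 and 72 h exchanged) and 40.1% (48 h exchanged). With 4 arrangements the smallest possible share is 0.25. Of 55 probes at least 2-fold apart at both 48 and 72 h, 42 went opposite ways, 40 of them higher at 48 h and lower at 72 h.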

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

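The tests of exchanged 48 h labels, of the mean spike-in level and of a term for the line at 48 h were chosen after the result was seen. The knockdown minus control differences of 48 h ran against those of 24 h (r = -0.60) and, over the tested mouse probes, those of 72 h (r = -0.27), as with miR-3096a-3p, miR-222-3p and miR-195a-5p. Against 72 h this depended on the probe set, since rho rose from -0.22 to 0.00872 with no filter and to 0.03 with probes of any species. Under the signal filters run on mouse probes rho stayed between -0.27 and -0.18. The correlations themselves have no test. In limma a term for the line at 48 h passed for 13 miRNAs with 1 residual degree of freedom, where simulations without any change made at least 1 call in 33 of 100 draws with each probe at its own spread and in 13 of 100 with spreads on the trend, with up to 7 and 3 calls. No explanation was excluded. A candidate explanation is an exchange of the 48 h labels between the lines: 2 of the 2 arrays of 48 h correlated better with the other line than with their own. This was read on the same values as the opposite differences. The same held for 5 of all 6 arrays. An array of 24 or 72 h has 1 array of 48 h on each side of this measure, so its result cannot count for or against an exchange.

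An array-wide difference in labelling or hybridization could also account for it, and the control probes gave mixed evidence. The control array of 48 h had the highest median over Hy3 control spots, 14132 against 4065 to 7767 on the others. It also had the highest median background, the largest spot SD (0.24) and the lowest mean spike-in level (8.48). The knockdown array of 48 h had the highest spike-in level (9.63). Neither lay at an end of the first principal component. Whether these values explain the pattern was not tested. Over 32 spike-in probes the 24 and 48 h differences correlated at -0.33 (95% bootstrap interval -0.57 to -0.02), and those of 48 and 72 h at -0.60. The bootstrap intervals over control probes cover the spread between probes read on the same arrays, not the spread between arrays. They are too narrow where probes move together. The first principal component of the mouse probes correlated with the mean spike-in level over the 6 arrays, though not past 0.05 after adjustment (Pearson r = 0.87, exact permutation p = 0.0375, adjusted p = 0.075 over 2 relations; Spearman rho = 0.89, exact permutation p = 0.0333, adjusted p = 0.0667). Without the 2 arrays farthest from the median spike-in level r was 0.83. Over 15 viral probes the 24 and 48 h differences correlated at -0.17 (interval -0.51 to 0.41), or at -0.11 without normalisation, and those of 48 and 72 h at 0.78, so these probes did not show the mouse pattern at 72 h.

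For scanner background, the first component correlated with mean background at a Pearson r of 0.0760 (exact permutation p = 0.888; Spearman rho = 0.14, exact permutation p = 0.803; 0.10 without the 2 farthest arrays). Its interval over 6 arrays, -0.78 to 0.84, leaves this open. A biological effect of the knockdown that turns at 48 h stays open and untested.

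The knockdown comparison called 0 miRNAs, and among the 10 splits of the 6 arrays into 3 and 3 the highest other count was 32. That split sets the knockdown arrays of 24 and 72 h with the control array of 48 h against the rest, and it points to a structure of the samples. It restates the opposite 48 h differences already seen and adds no independent evidence on their cause. For the lists the count was 0 with a highest other of 5, in the same split. With real counts of 0, all 10 splits gave counts as large by construction, and 10 splits are too few for a share under 0.05. The samples were kept as labelled throughout.

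Signal also appeared on probes outside the comparisons. Of the 57 viral miRNA probes 15 had an intensity of at least 50 on at least 3 arrays, led by mghv-miR-M1-8-5p with 1187 to 4231. The negative control probes reached 62.3 at most, on the knockdown array of 72 h, which is itself above 50. Of the 2256 unnamed probes, 584 met the same rule, and of the 1126 mouse probes 372 did. Whether any of these probes bound its named target was not tested.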

How the results depend on the processing

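Array weights and the line terms were chosen after the data were seen; all other alternatives were fixed before. The count of called miRNAs stayed at 0 for the knockdown comparison under every scaling, background, filter, probe set and variance setting run, and without the time block (no replicate block: 0 miRNAs and 0 lists), and the slope counts stayed at 0 except that the line by 48 h term, in place of the slope difference, called 13, a contrast built on the opposite 48 h differences. Leaving out each time point in turn gave 0 to 3 miRNAs and 0 to 3 lists for the knockdown comparison, the 3 in each case without 48 h. That fit has fewer arrays and drops the opposing difference; the cause was not tested further. Over the alternatives the smallest adjusted p of the knockdown comparison ran from 0.00840 to 1. With array weights, 2 lists passed. Both arrays of a time point got the same weight, 1.57 at 24 h, 0.71 at 48 h and 0.90 at 72 h. The opposing 48 h arrays thus counted least, as when they are left out. Whether this was the cause was not tested. The numbers of probes at least 2-fold apart at 24, 48 and 72 h, 46, 153 and 199, became 24, 51 and 89 over probes with signal on all 6 arrays and 84, 359 and 436 over probes of any species, since fewer or more probes were counted. At 1.5-fold they were 132, 271 and 310, by construction. At 24 and 48 h they were 115 and 245 with plain subtraction and 114 and 267 with the authors' ratios; the cause was not tested. The r of the 24 and 48 h differences ran from -0.63 to -0.49 and their rho from -0.59 to -0.38. Those of 48 and 72 h ran from -0.31 to -0.07 and from -0.27 to 0.03, with rho turning above 0 with no filter (0.00872) and with probes of any species (0.0296), over other probes. Those of 24 and 72 h ran from 0.13 to 0.29 and from 0.02 to 0.27. The median knockdown minus control difference over all tested probes ran from -0.15 with plain subtraction to 0.05 without 72 h, the only setting run that put it above 0. List medians changed sign in 59 of 395 refits. Low signal over background kept 754 mouse probes out of the tests.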

Other observations

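The hypothesis on hairpin arms was fixed before its result was seen. Of the 13 probes for other small RNAs with signal, 5 were picked after their values were seen. SNORD68, a small nucleolar RNA, had background-subtracted intensities of 595, 5319 and 199 in the knockdown and 1573, 253 and 3872 in the control at 24, 48 and 72 h. SNORD2 had 1877, 4403 and 1590 in the knockdown and 7982, 1503 and 6254 in the control. The U6 probe had 953, 2043 and 1403 in the knockdown and 893, 289 and 672 in the control, and 5S rRNA had 1527, 2972 and 2128 against 1883, 2523 and 917. SNORD110 varied less, between 118 and 313 over the 6 arrays. Over all 13 probes the knockdown minus control differences of 24 and 48 h correlated at -0.36 (95% bootstrap interval -0.75 to 0.05) and those of 48 and 72 h at -0.09. This interval too covers the spread between probes only.

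The first principal component of the mouse probes held 47.5% of the variance. Among the probes with the highest loadings, chosen after their values were seen, miR-16-5p had intensities of 193, 1630 and 47.3 in the knockdown and 941, 1.75 and 984 in the control, and let-7g-5p had 361, 2191 and 234 against 1413, 134 and 1380. At the other end, miR-882 had 412, 266 and 3847 in the knockdown and 457, 385 and 271 in the control.

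If signal followed the amount of each precursor, the 2 arms of a hairpin could be correlated over the arrays. Over 44 arm pairs the median r was 0.24, with 28 pairs above 0. Random pairs matched on brightness gave a 95% range of -0.21 to 0.26. The median lay just inside that range and its own bootstrap interval, -0.01 to 0.38, crossed the upper end, so the test left the question open.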
